A study of Mus musculus with 27 samples.

How the data were processed

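RNA from 27 samples of C57BL/6 mouse cells was measured on single-colour Illumina mouse bead arrays with 45281 probes. Per the labels, cells were lysed in TRIzol, RNA was cleaned on RNeasy columns with DNase I, and biotinylated cRNA was prepared with a TargetAmp kit. The deposited scanner table gave for each array the mean bead intensity of every probe, with no normalization between arrays and, as judged from its values, no background subtracted. The deposited table also gave a detection p-value per probe and array, which moved in steps of 1 in 936 and was read as the share of negative control beads at or above the probe. The deposited series matrix held intensity on a linear scale, quantile normalized between the 27 arrays as judged from its values, and was used only as an alternative. The software of the authors, the scanner settings and the genome build of the array are not stated. Control probes were not used here.

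Groups were taken from the labels: astrocytes, neurons, microglia, the ES-cell-derived microglia lines ESdM 20 and ESdM 22, MF, BM-DC and naive CD8 T cells. The labels do not spell out MF and BM-DC. Both came from bone marrow, and the letters are read here as macrophages and dendritic cells. The labels number the replicates but do not say whether they were separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. All ESdM descriptions carry the replicate number 3 while their titles run from 1 to 3, and the titles were used. The samples were spread over 10 chips. The microglia arrays and both ESdM lines shared 2 chips with each other and with no other group, the astrocyte and neuron arrays shared 1 chip, and all other groups were on chips of their own. No pair of arrays held identical values.

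The choices in this and the next paragraph were made before the data were examined. Intensities were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values, an offset of 16 and quantile normalization, and are given as log2 values. Probes with a detection p below 0.05 on at least 3 arrays were kept, which left 25001 probes. Of the 45281 probes, 34885 carried 1 gene symbol in the annotation table, 18 carried several and 10378 carried none here. For each symbol the probe with the highest mean was tested, so that a fold is that of 1 probe and other probes of the gene may give another, giving 12814 genes, of which 5249 had more than 1 probe past the filter. The other 4162 probes past the filter, without a single symbol, were tested only as probes. A limma model with 1 mean per group over all 27 arrays (19 residual degrees of freedom) and moderated variances gave each difference, with Benjamini-Hochberg adjustment over the genes of each comparison. A gene was called at an adjusted p below 0.05 and a difference of at least 1 on the log2 scale. ESdM stands for the mean of both lines with 3 arrays each. Where 1 of the groups compared had no array with the gene detected, the fold was taken after raising its arrays to their lowest detected value and is given as "at least", since a normalized value below that floor is no measurement. Where only some arrays of the lower group detected the gene, the fitted fold is given with their number. Near-identical genes, such as the guanylate binding protein, Serpina3 and H2 families, may share probes by cross-hybridisation, which was not tested. The number of arrays limits the precision.

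The genes named are, in each comparison, the 10 called genes with the largest rise and the 10 with the largest fall whose arrays did not overlap, leaving out clone names. From each list the text takes up to 2 called members in each direction, or with none called the 2 members with the largest difference, and any tested member of the microglia core list. For the signature the 15 genes with the largest smallest difference are named. Other named genes are stated to be chosen after their values were seen. The microglia signature holds the genes called higher on the arrays labelled microglia than in each of the astrocyte, neuron, MF, BM-DC and CD8 T cell groups. Distances are root mean square log2 differences over the tested genes between an array and the mean of the arrays labelled microglia, and MF and ESdM arrays were compared by an exact two-sided permutation test over 210 splits.

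A set of 30 gene lists with 622 entries was fixed, of which 576 matched a named probe and 497 were tested. They cover microglia core, macrophage lineage, blood-derived macrophage, dendritic cell, MHC class I, MHC class II, astrocyte, neuron, naive CD8 T cell, oligodendrocyte lineage, endothelial and mural, fibroblast, B cell, granulocyte and mast cell, pluripotency, haematopoietic progenitor and erythroid, cell cycle, interferon response, inflammatory cytokines, alternative activation, complement and phagocytic receptors, toll-like receptors and adaptors, lysosome, disease-associated microglia, cholesterol synthesis, glycolysis, purinergic receptors, TGF-beta signalling, Y-linked, and RNA stress and dissociation response genes. Lists with at least 5 tested members (29 lists) were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Counts "adjusted over the list alone" use Benjamini-Hochberg over the members of that list. In a step added after the data were seen, genes with a mean of at least 7 were ordered along the genome by the RefSeq table and the median difference of each block of 50 neighbours was compared with the most extreme blocks of 1000 permuted gene orders (95 percent range). The number of blocks shared by a pair of differences was compared with that in the same permuted orders.

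Alternatives were another background correction (normexp with offset 50), none, median scaling, the series matrix, no filter or a stricter one (detection p below 0.01), all probes, trended robust variances, array weights, the replicate number or the chip as a block, the arrays of each shared chip alone, no minimum fold, an estimated list correlation, fry, a Spearman distance and leaving out each array in turn. On simulated data with 200 changed genes of 3 sizes, calls recovered 100% of genes changed by 1.5 on the log2 scale in ESdM vs microglia and in microglia vs MF, 98.5% in microglia vs CD8 T cells and 97.0% in ESdM 22 vs ESdM 20, with at most 1 false call. The signature step recovered 200 of 200 planted genes, the shared step 100 of 100, the list step 5 of 5 with 1 list not planted, and the block step 4 of 4. In the list step the noise was drawn independently for each gene, so it does not test the preset inter-gene correlation of 0.01. Several comparisons use the same microglia arrays, so their counts are not independent. In 20 simulations with no effect the shared signature and the calls shared by both ESdM lines held 0 genes. Such simulations cannot measure the overlap that shared arrays add where real differences exist.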

Results

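RNA levels were measured on 27 arrays in 8 groups of mouse cells. Both ESdM lines, grown from embryonic stem cells and in culture for more than 51 days, had 3 arrays each (ESdM 20 and ESdM 22). Cultured cells labelled microglia, astrocytes and embryonic neurons had 3 arrays each, MF 4, BM-DC 3 and naive CD8 T cells from spleen 5. The ages taken from the labels were day 3 for microglia and astrocytes and embryonic day 15 to 16 for neurons. They were day 7 for MF and BM-DC and 6 to 8 weeks for CD8 T cells. Where the ages of the groups differ, age cannot be separated from the cell type. The median raw intensity per array was at least 106 in astrocytes, 101 to 112 in neurons, 93.2 to 95.6 on the arrays labelled microglia, 91.6 to 95.4 in ESdM 20, 92.6 to 94.3 in ESdM 22, 80.1 to 95.4 in MF, 27.6 to 28.6 in BM-DC and 86.8 to 109 in CD8 T cells. Between 14247 and 17533 probes were detected per array. Levels are log2 normalized intensities, for which undetected genes lie near 4.3.

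The comparisons ask how far cells grown from embryonic stem cells resemble cultured microglia, and how both differ from other primary cells. Genes of the macrophage lineage list were detected on the arrays labelled microglia (n = 3). Laptm5 was at 13.40 and Fcer1g, an immunoglobulin receptor chain, at 12.66. Adgre1, which encodes F4/80, was at 10.66 and Csf1r, the receptor for CSF1, at 9.04 (these 2 chosen after their values were seen). Laptm5 was higher on the CD8 T cell arrays, at 13.545 to 13.859, so it does not mark myeloid cells alone. The astrocyte arrays had Laptm5 at 12.617 to 13.014, Fcer1g at 10.844 to 11.571, Adgre1 at 9.803 to 10.671 and Csf1r at 8.383 to 9.472. Microglia core genes were largely not detected on the arrays labelled microglia. Of 22 named genes of that list, 14 were detected on none of these arrays and 6 on all, and Fcrls (4.27), Cx3cr1 (4.48), Tmem119 (4.50), P2ry12 (4.28), Olfml3 (4.20) and Sparc (4.35) lay at the floor. Those detected on all 3 arrays were Bin1 (9.07), Golm1 (8.92), Tgfbr1 (8.74), Selplg (8.27), Sall1 (5.46) and Lpcat2 (5.35). Neurons and naive CD8 T cells also had 6 of the 22 detected on all their arrays. In neurons and CD8 T cells Bin1 was at 8.9 and 8.7, Golm1 at 8.48 and 9.57 and Tgfbr1 at 8.53 and 9.38. Selplg was at 4.33 and 11.92 there, Sall1 at 5.04 and 4.52 and Lpcat2 at 4.62 and 4.43. ESdM 20 and ESdM 22 had 11 core genes each detected on no array. The astrocyte arrays had 17 of the 22 detected on all arrays, with Sparc at 12.62, Fcrls at 12.34, Cx3cr1 at 9.44, Olfml3 at 8.11, Tmem119 at 6.07 and P2ry12 at 5.02. The MF arrays had 13 and the BM-DC arrays 10, with Fcrls at 9.41 and 9.55.

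**Figure D1:**
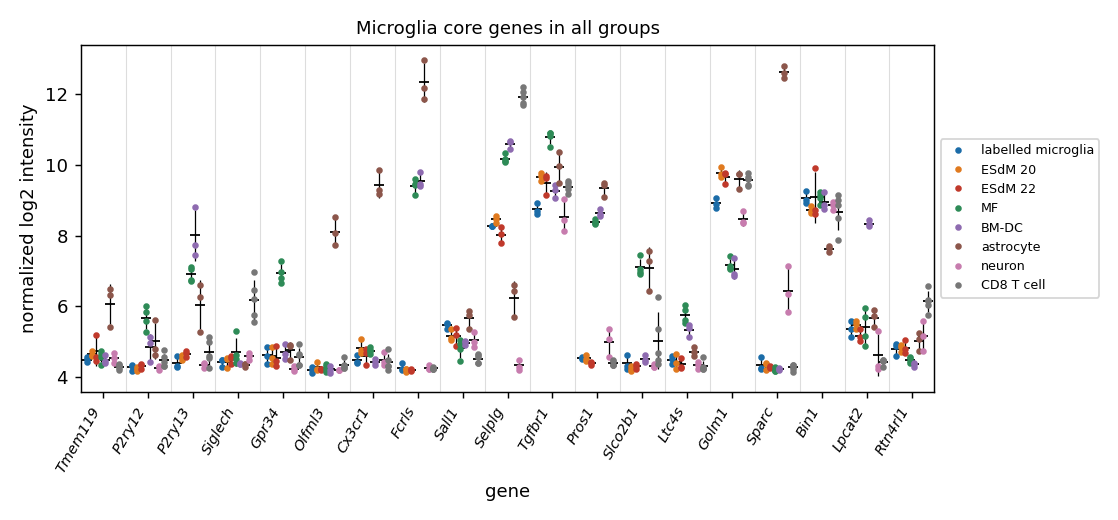
Log2 normalized intensity of microglia core genes on each array of the 8 groups (points), with the mean and SD of each group. Fcrls was at 4.27 on the arrays labelled microglia and at 12.34 on the astrocyte arrays.

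Across the 12814 genes tested, ESdM arrays lay closest to the arrays labelled microglia. The root mean square log2 difference to the mean of those arrays was 0.438 ± 0.0376 (SD, n = 6) for ESdM and 1.08 ± 0.0173 (SD, n = 4) for MF, a difference of 0.638 (exact two-sided permutation p = 0.00476, the smallest that 210 splits allow). The 6 ESdM arrays are replicates of ESdM 20 and ESdM 22 alone, and the splits treat them as exchangeable. The p-value therefore does not measure the spread between lines. The root mean square difference was 0.419 for ESdM 20, 0.457 for ESdM 22, 1.26 for BM-DC, 1.55 for CD8 T cells, 1.58 for astrocytes and 1.89 for neurons. The arrays labelled microglia lay 0.164 to 0.185 from the mean of the others. The Pearson correlation of group means with the microglia label, across genes, which are not independent replicates, was 0.984 for ESdM, 0.884 for MF, 0.839 for BM-DC, 0.759 for CD8 T cells, 0.746 for astrocytes and 0.638 for neurons. ESdM shared chips with the microglia label and MF did not, so for MF the chip and the cell type cannot be separated.

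**Figure D2:**
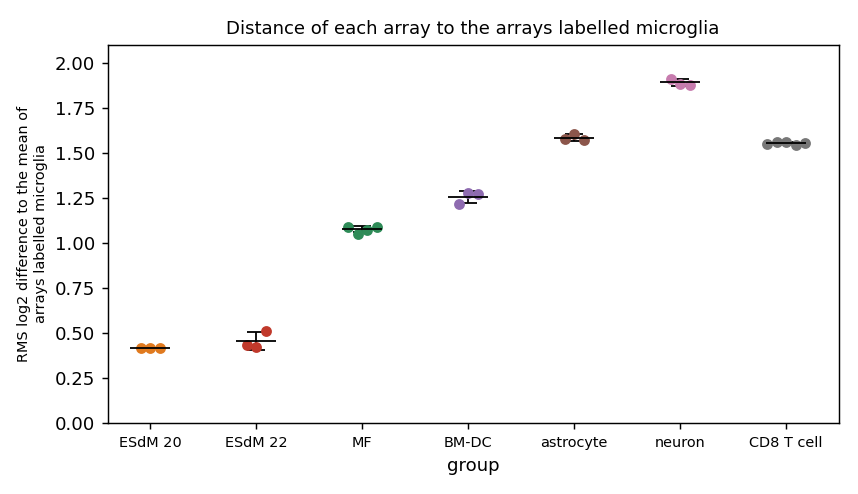
Root mean square log2 difference of each array to the mean of the arrays labelled microglia, over the genes tested, for 7 groups (points are arrays). ESdM arrays lay at 0.438 on average and MF arrays at 1.08.

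Against the arrays labelled microglia, ESdM cells had much less RNA of interferon-induced genes. Gbp2, an interferon-induced GTPase, fell 420.4-fold, from 13.59 to 4.87 (log2 difference -8.72, SE 0.138, n = 3 and 6, limma adjusted p = 8.7e-25); its 2 other probes gave log2 -4.02 and -0.74, of which only the larger fall was called. The chemokine genes Ccl5 and Cxcl10 fell 86.3-fold and 24.2-fold, and Cxcl9 at least 78.2-fold. Gbp3 and Igtp, further GTPases of this kind, fell 46.3-fold and 30.9-fold, and Oasl2, an antiviral gene, 32.6-fold. Acod1, which makes itaconate, fell 42.4-fold, Cish, a suppressor of cytokine signalling, 20.5-fold, and the protease inhibitor gene Serpina3f at least 104-fold. Of the 6 ESdM arrays, Ccl5, Cxcl10 and Cish were detected on 3, Gbp2 on 4 and Oasl2 and Acod1 on 5. Rises were smaller. Tmem273 rose 5.40-fold (log2 2.43, SE 0.187, adjusted p = 4.0e-10), Lipa, the lysosomal acid lipase, 4.87-fold, Clk1, a splicing kinase, 4.41-fold and Hp, haptoglobin, 3.93-fold. Mir17hg, the host gene of the miR-17-92 cluster, rose 3.51-fold, Bcl6, a transcriptional repressor, 3.35-fold and Abcc3, a transporter, 3.32-fold. Arhgef2 (4.04-fold) and Tnfsfm13 (3.39-fold) rose at 1 probe only, with their 3 and 1 other probes not called, and 1 of 2 other probes of Tmem273 was called. The other probes of Oasl2 and Cxcl10 fell less, by log2 -1.49 and -2.78. ND4L, a mitochondrial complex I gene, rose 3.67-fold (adjusted p = 0.0094), a call lost without background correction (adjusted p = 0.0864) and on the series matrix values (adjusted p = 0.112). Over all alternatives for ND4L, ESdM vs microglia, adjusted p ran from 1.05e-05 to 0.112. Abcc3 and Mir17hg missed the minimum fold on the series matrix values, with log2 0.86 and 0.96, and Abcc3 also without background correction, with 0.94.

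The interferon response list moved most, with 14 of 25 genes lower in ESdM, 0 higher and 14 lower adjusted over the list alone (camera adjusted p = 1.8e-30; adjusted p = 0.00559 with an estimated correlation). Without background correction, and on the series matrix values, 9 were lower. Of 17 MHC class I genes 9 were lower (9 adjusted over the list alone), among them Psmb9, an immunoproteasome subunit, 5.07-fold and H2-T23 5.00-fold (adjusted p = 5.8e-19; adjusted p = 0.000529 with an estimated correlation). Of 22 inflammatory cytokine genes 8 were lower (8 adjusted over the list alone), with Ccl4 at 5.46-fold (adjusted p = 2.2e-10; adjusted p = 0.0487 with an estimated correlation). In the dendritic cell list 2 of 19 genes were lower, Cd40 4.44-fold and Slamf7 at least 1.95-fold (adjusted p = 0.000386; adjusted p = 0.0487 with an estimated correlation). The blood-derived macrophage list was lower (adjusted p = 0.00691; adjusted p = 0.128 with an estimated correlation), with Saa3, an acute-phase gene, 5.26-fold and Ifitm3 3.08-fold among 3 lower genes of 19 and Hp alone higher. In the MHC class II list only Cd74, the invariant chain, fell, 5.89-fold, of 12 (adjusted p = 0.0195; adjusted p = 0.472 with an estimated correlation), a list call that was also lost without microglia replicate 1 (adjusted p = 0.057) and with fry (adjusted p = 0.0812; range over the alternatives 0.000826 to 0.472). The glycolysis list shifted down with 0 of 16 genes called (adjusted p = 6.2e-05; adjusted p = 0.117 with an estimated correlation); the largest log2 differences were -0.83 for Pfkp and -0.68 for Pgam1. The cholesterol synthesis list shifted up with 0 of 15 called (adjusted p = 0.00691; adjusted p = 0.372 with an estimated correlation), led by Cyp51 and Hsd17b7 at log2 0.995 and 0.819. The lysosome list shifted up with only Lipa called of 28 (adjusted p = 0.0102; adjusted p = 0.372 with an estimated correlation), a call also lost with median scaling (adjusted p = 0.0686; range over the alternatives 0.00137 to 0.372).

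**Figure D3:**
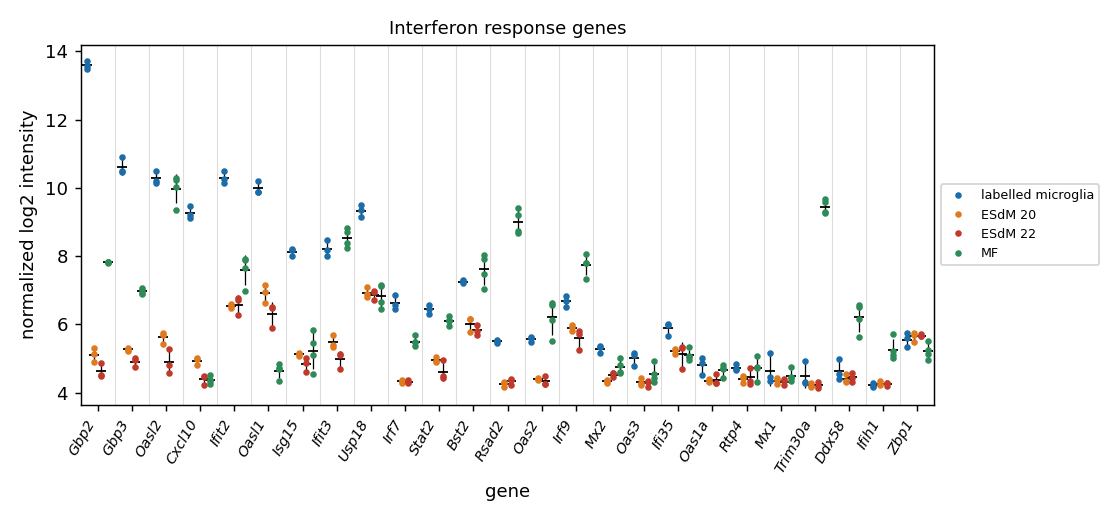
Log2 normalized intensity of the interferon response genes on each array labelled microglia and on the ESdM 20, ESdM 22 and MF arrays. Gbp2 was at 13.59 on the arrays labelled microglia and at 4.87 on average in ESdM.

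No other list was called in ESdM against the arrays labelled microglia, although single members were. In the macrophage lineage list 4 of 21 genes fell, among them the transcription factor gene Irf8 3.17-fold and C1qb, a complement subunit, at least 8.29-fold (list adjusted p = 0.11, and 0.0166 with median scaling; range over the alternatives 0.0166 to 0.797). C1qb and C1qc (at least 2.45-fold) were the 2 lower of 25 complement and phagocytic receptor genes (3 adjusted over the list alone). In the disease-associated microglia list Apoe, a lipid carrier, rose 2.31-fold and the growth factor gene Igf1 2.08-fold, while Cd52 fell 9.02-fold and Csf1 3.27-fold, of 18. Igf1 and Tgm2 (2.05-fold, detected on 2 of 3 arrays labelled microglia) were the 2 risen of 15 alternative activation genes, and P2ry6, a nucleotide receptor, the 1 risen of 13 purinergic genes (3.14-fold). Fos (2.93-fold) and Dusp1 (2.31-fold) rose and Ier3 (2.096-fold) fell among 18 RNA stress genes. Single falls were Smurf1 (2.602-fold) of 17 TGF-beta genes, Klf4 (2.64-fold) of 8 pluripotency genes and Ly6c1 (at least 4.07-fold) of 13 endothelial and mural genes, in which Acta2 rose 2.69-fold. Cpe rose 2.14-fold as the 1 called of 19 astrocyte genes. None was called of 19 microglia core genes, where the largest log2 differences were 0.83 for Tgfbr1 and 0.80 for Golm1, of 24 cell cycle genes (Kif11 0.65, Cdc20 0.54) or of 20 toll-like receptor genes (Tlr1 0.89, Tlr13 0.79). None was called either of 22 neuron genes (Ina 0.74, Syn1 0.45), 17 naive CD8 T cell genes (Cd28 0.72, Cd8b1 0.21), 7 oligodendrocyte genes (Cnp -0.36, Mag -0.21), 9 fibroblast genes (Fbln1 -0.19, Pdgfra -0.12), 7 B cell genes (Blnk 0.49, Ebf1 0.18), 17 granulocyte and mast cell genes (S100a8 -0.66, Mmp9 -0.21), 12 haematopoietic progenitor genes (Tal1 0.29, Meis1 0.24) or 3 Y-linked genes (Uty -0.06, Kdm5d 0.04).

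In all, 265 of 12814 genes were called between ESdM and the arrays labelled microglia, 77 higher and 188 lower, and 2755 genes had an unadjusted p below 0.05. The arrays of all 265 did not overlap, against 20.8% of all genes without overlap and 2.38% by chance. With the chip as a fixed block 270 genes were called. Within the first shared chip alone, which held a single array labelled microglia, 270 were called, and within the second, with 2 such arrays, 174. Without background correction 122 were called, and on the series matrix values 105. Against the same arrays, ESdM 20 had 276 calls (89 higher, 187 lower) and ESdM 22 had 267 (66 higher, 201 lower). The lines shared 49 higher and 170 lower genes, with 0 in opposite directions, where independent calls would share 0.458 and 2.93. Both lines were compared with the same arrays labelled microglia, so their calls are not independent. Simulations with no effect gave 0 shared calls, but almost nothing is called with no effect. They therefore do not measure the overlap that the shared arrays add. Of the interferon response genes 13 were lower in ESdM 20 and 15 in ESdM 22, and of the MHC class I genes 9 and 10.

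Between ESdM 22 and ESdM 20 the limma test called 0 genes at n = 3 and 3, with 527 genes at an unadjusted p below 0.05, and 12.9% of genes had arrays that did not overlap, against 10% by chance. Below the minimum fold, Ffar4, a fatty acid receptor gene, differed by log2 -0.98 (SE 0.14, adjusted p = 0.00328), Scgb1a1, a secretoglobin gene, by -0.61 (SE 0.102, adjusted p = 0.0183) and Draxin, an axon guidance gene, by 0.71 (SE 0.123, adjusted p = 0.0247). The cholesterol synthesis list was lower in ESdM 22 (camera adjusted p = 0.000888; adjusted p = 0.902 with an estimated correlation), with Dhcr7 at log2 -0.66 and Sqle at -0.51. The interferon response list was also lower there (adjusted p = 0.0357; adjusted p = 0.902 with an estimated correlation), with Oasl2 at -0.74 and Oasl1 at -0.61.

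A set of 348 genes was higher on the arrays labelled microglia than in each of astrocytes, neurons, MF, BM-DC and CD8 T cells, and 284 of them (81.6%) were also higher in ESdM than in each of these, where independent lists would share 11.1. Both sets are defined against the same arrays of these groups, so they are not independent and 11.1 is no yardstick for the overlap. Rhox5, a homeobox gene of the reproductive tract, led with 13.12 on the arrays labelled microglia, 13.15 in ESdM 20 and 13.08 in ESdM 22, against 4.29 to 4.42 elsewhere. Flt1, a VEGF receptor gene, was at 11.95, Slco4a1, a transporter gene, at 11.52 and Amhr2, the receptor gene for anti-Müllerian hormone, at 10.13; 1 other probe each of Flt1 and Slco4a1 was not called against MF. Arhgap8 (9.20), Nckap5l (9.11), Tex101 (8.80), Hoxc6 (8.45), Abcc2 (8.38), Tcam1 (8.36) and Ptpn14 (8.24) were also shared with ESdM. Serpina3f (11.33), Cxcl9 (10.91), Gbp2 (13.59) and Oasl1 (9.99) belonged to the set but were not higher in ESdM than in every other group. Of the 64 genes not shared with ESdM, 21 were called lower in ESdM than on the arrays labelled microglia. The 348 genes held 0 of 19 microglia core genes, 0 of 21 macrophage lineage genes, 5 of 25 interferon response genes and 4 of 24 cell cycle genes. Astrocyte arrays carried microglia core RNA. Without the astrocyte comparison, a choice made after the data were seen, the set held 423 genes, of which 345 were shared. With median scaling the set held 221 genes with 175 shared, and without background correction 193 with 157.

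Against MF, the arrays labelled microglia had less RNA for complement, lysosome and MHC class II genes, list calls that were lost with adjusted p of 0.075 to 0.234 with an estimated correlation. Ms4a7, a macrophage membrane gene, was 156.0-fold lower (log2 -7.29, SE 0.23, n = 3 and 4, limma adjusted p = 6.0e-19), Mmp12, macrophage elastase, 147.0-fold, Cd93, a complement-associated receptor gene, 104.8-fold and Selenop, a selenium transport gene, 94.0-fold. Smpdl3a, Npy, Lamtor4 and Cnrip1 were lower by at least 112-fold, 86.2-fold, 83.3-fold and 77.1-fold. Rtl8a was undetected there and at 11.46 in MF, though its other probe was not called. Xist, the X inactivation RNA, was at least 67.1-fold lower. Flt1 was 161.3-fold higher, Slpi, a protease inhibitor gene, 156.2-fold, Slco4a1 75.9-fold, Fkbp11 66.8-fold, Saa3 59.4-fold and Gbp2 54.3-fold. Rhox5, Serpina3f, Septin3 and Cxcl9 were higher by at least 369-fold, 106-fold, 80.1-fold and 79.6-fold. Cd93 was detected on 1 of 3 arrays labelled microglia, Flt1 and Saa3 on 1 of 4 MF arrays and Slpi on 3. Of the other probes of Septin3 and Gbp2, 2 of 4 and 1 of 2 were called. The limma fit called 2882 genes, 1409 higher and 1473 lower, and 1580 without background correction. Median scaling gave 755 higher and 2499 lower.

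Of 21 macrophage lineage genes 14 were lower on the arrays labelled microglia than in MF (15 adjusted over the list alone), led by C1qc 50.8-fold and C1qb 21.3-fold (camera adjusted p = 2.6e-06; adjusted p = 0.198 with an estimated correlation). Of 28 lysosome genes 16 were lower, Lipa 26.3-fold and Ctsh at least 64.8-fold, while Ctsk, a collagen-degrading cathepsin gene, was 28.4-fold higher (adjusted p = 2.3e-07; adjusted p = 0.075 with an estimated correlation). Of 25 complement and phagocytic receptor genes 15 were lower and Stab1 was higher (adjusted p = 1.5e-06; adjusted p = 0.075 with an estimated correlation). Of 12 MHC class II genes 7 were lower, H2-Aa at least 53.3-fold and H2-Ab1 at least 37.0-fold (adjusted p = 0.0024; adjusted p = 0.234 with an estimated correlation). MHC class I genes went both ways, with 4 higher and 3 lower of 17 (adjusted p = 0.256). Purinergic receptor genes were lower for 7 of 13, P2ry6 61.6-fold and P2ry14 43.9-fold, detected on 1 of 3 arrays labelled microglia (adjusted p = 0.0024; adjusted p = 0.109 with an estimated correlation). Of 19 microglia core genes 9 were lower, Fcrls at least 27.2-fold and Pros1 at least 13.4-fold, and Golm1 was 3.36-fold higher (adjusted p = 0.00461; adjusted p = 0.198 with an estimated correlation). The disease-associated list had 9 lower, led by Axl at least 25.7-fold, and 3 higher, led by Cst7 14.02-fold, of 18 (adjusted p = 0.00417; adjusted p = 0.136 with an estimated correlation). Lists called with adjusted p of 0.0283 to 0.0459, none below 0.05 with an estimated correlation (adjusted p of 0.198 to 0.462 with an estimated correlation), were toll-like receptors (10 lower, Tlr2 higher 7.35-fold), alternative activation (5 lower, Tgm2 45.2-fold, with Mgl2 and Stab1 higher), TGF-beta signalling (4 lower, Skil 6.21-fold, with Smurf1 higher) and glycolysis (3 higher, Pfkm 5.31-fold). Interferon response genes went both ways, with 8 higher and 5 lower of 25 (Gbp2 higher, Trim30a lower 31.0-fold; adjusted p = 0.146), as did 6 and 7 of 22 cytokine genes (Ccl5 higher 39.4-fold, Ccl7 lower 42.5-fold). Of the 3 arrays labelled microglia, Trim30a was detected on 1 and Tgm2 and Skil on 2. These groups shared no chip.

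Against BM-DC, the arrays labelled microglia lacked much of the RNA for MHC class II, with 11 of 12 genes lower (11 adjusted over the list alone), H2-Ab1 at least 226.8-fold and H2-Aa at least 142.7-fold (log2 SE 0.372 and 0.502, n = 3 and 3; camera adjusted p = 1.5e-08; adjusted p = 0.0224 with an estimated correlation). Clec4n, the gene of dectin-2, was 319.7-fold lower and P2ry14 229.1-fold. Tgfbi, Cstdc4, Pdpn, Serpinb2, Ccl6, a chemokine gene, and Spint1 were lower by at least 280.9-fold, 219.4-fold, 203.8-fold, 166.4-fold, 158.7-fold and 147.6-fold. Flt1 was 153.1-fold higher, Septin3 83.5-fold and Tmem176b 41.2-fold. Rhox5, Serpina3f, Cxcl9, Amhr2, Cpe, Arhgap44 and Ddah1 were higher by at least 368.5-fold, 106.0-fold, 79.5-fold, 46.3-fold, 45.9-fold, 35.5-fold and 31.4-fold. P2ry14 was detected on 1 of 3 arrays labelled microglia and Il1b on 2, and of the 3 BM-DC arrays Septin3 and Tmem176b on 1 and Flt1 on 2. The other probe of Flt1 was not called, and of those of Septin3 and Amhr2 2 of 4 and 1 of 2 were. Cell cycle genes were higher for 21 of 24, Cdc20 18.0-fold and Aurka 17.3-fold (adjusted p = 1.1e-07; adjusted p = 0.187 with an estimated correlation). Of 19 dendritic cell genes 12 were lower, the costimulatory gene Cd80 30.4-fold and Kit at least 19.9-fold, and Cd40 was 4.67-fold higher (adjusted p = 1.4e-05; adjusted p = 0.0166 with an estimated correlation). Granulocyte genes were lower for 10 of 17, S100a8 48.2-fold and S100a9 at least 32.1-fold (adjusted p = 8.4e-08; adjusted p = 0.0165 with an estimated correlation), and blood-derived macrophage genes for 15 of 19 with Hp higher (adjusted p = 1.1e-07; adjusted p = 0.00997 with an estimated correlation). Purinergic genes were lower for 7 of 13 (adjusted p = 0.0166 with an estimated correlation) and alternative activation genes for 7 of 15 with Stab1 higher (adjusted p = 0.0422 with an estimated correlation). Inflammatory cytokine genes were lower for 13 of 22, Il1b 36.9-fold and Cxcl2 at least 66.7-fold, with Ccl5 higher (adjusted p = 1.4e-05; adjusted p = 0.118 with an estimated correlation). Also called, with adjusted p of 5.8e-05 to 0.0368 (adjusted p of 0.0972 to 0.301 with an estimated correlation), were the lysosome (14 lower, 2 higher), macrophage lineage (10, 1), complement (9, 3), toll-like receptor (8, 0), RNA stress (8, 1, led by Egr1 and Fosb), disease-associated (9, 3), naive CD8 T cell (5, 0), TGF-beta (6, 1) and microglia core (5, 1) lists. In all 3499 genes were called, 1909 higher and 1590 lower, and 2035 without background correction. Median scaling turned the majority to lower, with 1537 higher and 1900 lower. The groups shared no chip, and the median raw intensities of the BM-DC arrays were below those of all other arrays.

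Against astrocytes, 18 of 19 astrocyte genes were lower on the arrays labelled microglia (18 adjusted over the list alone), the glutamate transporter gene Slc1a3 at least 383.2-fold and Sox9 at least 347.5-fold (SE 0.251 for Slc1a3, n = 3 and 3; camera adjusted p = 7.2e-11; adjusted p = 0.165 with an estimated correlation). Igfbp5, Ccn2, Fhl1, the cyclin gene Ccnd2, the oligodendrocyte factor Olig1, Thy1, Prelp and F2r were lower by at least 718.9-fold, 492.4-fold, 463.4-fold, 415.7-fold, 411.5-fold, 352-fold, 341.1-fold and 339.3-fold, and Acta2, smooth muscle actin, by 535.6-fold. Ctsk was 489.1-fold higher, Rhox5 416.9-fold, Ccl5 92.8-fold, Tnfaip2 85.9-fold and Emilin2 59.1-fold; Rhox5, Ccl5 and Emilin2 were each detected on 1 of 3 astrocyte arrays. Slpi, Serpina3f, Mcoln3, Cxcl9 and Acod1 were higher by at least 178-fold, 109.8-fold, 83.99-fold, 82.4-fold and 55.4-fold. Microglia core genes were lower for 9 of 19, Sparc at least 252.7-fold and Fcrls at least 207.5-fold, and higher for Selplg (4.07-fold) and Bin1 (2.70-fold; adjusted p = 0.00677; adjusted p = 0.276 with an estimated correlation). The macrophage lineage list had 10 higher, Fcgr3 7.44-fold and Cd53 7.04-fold, and 3 lower of 21, C1qc 17.6-fold and C1qa at least 7.99-fold. The astrocyte arrays thus carried RNA of macrophage lineage and microglia core genes. Cell cycle genes were higher for 22 of 24, led by Aurka 14.7-fold (adjusted p = 3.9e-06; adjusted p = 0.451 with an estimated correlation), and MHC class I genes for 13 of 17, led by H2-D1 14.6-fold (adjusted p = 3.3e-05; adjusted p = 0.145 with an estimated correlation). Fibroblast genes were lower for 6 of 9 (adjusted p = 0.00032; adjusted p = 0.145 with an estimated correlation). The interferon response list had 9 higher and 4 lower (adjusted p = 0.0276; adjusted p = 0.621 with an estimated correlation). In all 4536 genes were called, 2127 higher and 2409 lower, and 2744 without background correction. The groups shared no chip.

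Against neurons, macrophage lineage genes were higher on the arrays labelled microglia for 18 of 21, Laptm5 308.5-fold and Fcer1g at least 268.1-fold (limma SE 0.161 and 0.407, n = 3 and 3), and 21 of 22 neuron genes were lower, the tau gene Mapt at least 490.6-fold and Stmn2 at least 427.1-fold; the counts adjusted over the list alone were also 18 and 21. Ctsk was 598.4-fold higher, the galectin gene Lgals3 549.9-fold, the lysozyme gene Lyz1 501.4-fold, Rhox5 416.4-fold, Gpnmb 317.4-fold and Dab2 282.3-fold, with Gbp2 and Lyz2 at least 509.6-fold and 181.3-fold; 2 other probes of Lyz1 were not called. Nrep was 875.6-fold lower and Rtn1 392.5-fold, and Sox11, Fxyd6, Snurf, Rtl8a, Nme7 and the synaptotagmin gene Syt4 were lower by at least 546.6-fold, 470.0-fold, 451.5-fold, 433.1-fold, 366.2-fold and 356.5-fold. Nrep and Rtn1 were each detected on 1 of 3 arrays labelled microglia, Ctsk and Rhox5 on 1 of 3 neuron arrays and Lgals3, Lyz1 and Dab2 on 2. For Nme7, 1 of 7 other probes was called the opposite way and 2 the same way, and 1 of 2 was called for Gbp2 and Lyz2, 2 of 3 for Snurf and 3 of 4 for Rtn1. Lysosome genes were higher for 22 of 28, toll-like receptor genes for 15 of 20, MHC class I genes for 15 of 17, interferon response genes for 14 of 25 and cell cycle genes for 22 of 24. Of 19 microglia core genes only Selplg was higher (at least 12.8-fold) and only Sparc lower (at least 3.48-fold). In all 5192 genes were called, 2622 higher and 2570 lower, and 3307 without background correction.

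Against naive CD8 T cells, 15 of 17 naive CD8 T cell genes were lower on the arrays labelled microglia (15 adjusted over the list alone), the chromatin organiser Satb1 at least 404.9-fold and Thy1 at least 266.4-fold (limma SE 0.267 and 0.171, n = 3 and 5). The T cell receptor gene Trbv13-2, Ets1, Sh2d2a, Cd3e, Cd3d, Gimap6, Cd3g and Rasgrp1 were lower by at least 434.4-fold, 390.4-fold, 249.3-fold, 249.1-fold, 245.6-fold, 238-fold, 234.2-fold and 202.2-fold. Higher were Ctsk (594.9-fold), Gpnmb (511.3-fold), the metallothionein gene Mt1 (268.5-fold), Tnfaip2 (223.6-fold), Lyz2 (183.1-fold), Cd63 (178.4-fold), the lipase gene Lpl (167.7-fold; its other probe was not called), and Rhox5, Dab2 and Flt1 by at least 356.9-fold, 305.9-fold and 158.1-fold. Of the 5 CD8 T cell arrays, Ctsk, Tnfaip2 and Cd63 were detected on 1, Lyz2 and Lpl on 2 and Gpnmb on 3. The other probe of Flt1 was not called, and 1 of 2 was for Lyz2 and Ets1. Of 21 macrophage lineage genes 15 were higher and Ptprc and Cd53 lower, with levels that varied between the CD8 T cell arrays. Cell cycle genes were higher for 17 of 24 and cholesterol synthesis genes for 10 of 15, while 11 of 18 RNA stress genes were lower and 2 higher. In all 4205 genes were called, 2307 higher and 1898 lower, and 2600 without background correction. With median scaling most were lower, 2536 against 1768 higher. Neither the neuron nor the CD8 T cell arrays shared a chip with the arrays labelled microglia.

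ESdM also had less RNA than MF for complement, MHC and lysosome genes, list calls that were lost with adjusted p of 0.114 to 0.279 with an estimated correlation. Of 25 complement and phagocytic receptor genes 15 were lower and Stab1 was higher (camera adjusted p = 6.7e-07; adjusted p = 0.114 with an estimated correlation). Of 21 macrophage lineage genes 15 were lower in ESdM (15 adjusted over the list alone), C1qb at least 176.9-fold and C1qc at least 124.6-fold (SE 0.351 and 0.35, n = 6 and 4; camera adjusted p = 6.7e-07; adjusted p = 0.177 with an estimated correlation). Ms4a7 was 131.9-fold lower, Cd93 108.8-fold, Mmp12 108.4-fold and the chemokine gene Ccl7 103.5-fold, and Rtl8a, Smpdl3a, Lgals3bp and Lamtor4 at least 114.6-fold, 113.6-fold, 106.2-fold and 84.4-fold. Higher were Rhox5 (at least 366.2-fold), Flt1 (114.0-fold), Slpi (97.0-fold), Slco4a1 (88.3-fold), Fkbp11 (50.1-fold), Myadml2 (39.99-fold), and Septin3, Amhr2, Hp and the filamin gene Flnc by at least 52.1-fold, 52.0-fold, 36.8-fold and 32.3-fold. Of the 6 ESdM arrays, Cd93 was detected on 2, Ccl7 on 4 and Oasl2 on 5, and of the 4 MF arrays Flt1 and Myadml2 on 1 and Slpi and Oasl1 on 3. The other probes of Rtl8a, Flt1 and Slco4a1 were not called, and of those of Septin3 and Amhr2 2 of 4 and 1 of 2 were. Interferon response genes were lower for 13 of 25, led by Oasl2 26.4-fold and Trim30a at least 28.4-fold, with Oasl1 higher 3.88-fold (adjusted p = 0.000216; adjusted p = 0.357 with an estimated correlation). MHC class II genes were lower for 8 of 12 (adjusted p = 0.000156; adjusted p = 0.177 with an estimated correlation), MHC class I genes for 9 of 17 with Nlrc5 higher (adjusted p = 0.00852; adjusted p = 0.279 with an estimated correlation) and lysosome genes for 14 of 28 with Ctsk higher (adjusted p = 1.2e-05; adjusted p = 0.167 with an estimated correlation). Microglia core genes were lower for 9 of 19, Fcrls at least 27.5-fold, with Golm1 5.86-fold higher (adjusted p = 0.00852; adjusted p = 0.225 with an estimated correlation). In all 3030 genes were called, 1478 higher and 1552 lower, and 1702 without background correction. Median scaling gave 853 higher and 2465 lower.

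Against BM-DC, ESdM had 3797 genes called, 2038 higher and 1759 lower, and 2287 without background correction. With median scaling 1743 were higher and 1993 lower. MHC class II genes were lower for 11 of 12, H2-Ab1 at least 229.9-fold and H2-Aa at least 144.7-fold (limma SE 0.322 and 0.435, n = 6 and 3), dendritic cell genes for 12 of 19, cytokine genes for 16 of 22 and interferon response genes for 16 of 25 with Oasl1 higher; adjusted over the list alone these counts stayed the same. Clec4n was 348.3-fold lower, Wfdc17 228.6-fold and Cish 198.5-fold, and Tgfbi, Cstdc4, P2ry14, Pdpn and Serpinb2 were lower by at least 284.7-fold, 222.4-fold, 207.1-fold, 206.6-fold and 168.6-fold. Cell cycle genes were higher for 21 of 24 and cholesterol synthesis genes for 8 of 15. Higher were also Rhox5 (at least 365.9-fold), Flt1 (108.2-fold), Apoe (74.6-fold), Tmem176b (68.0-fold), the adhesion gene Cadm1 (57.1-fold), Septin3 (54.2-fold), and Cpe, Amhr2, Myadml2 and Sult4a1 by at least 98.0-fold, 51.9-fold, 37.0-fold and 32.1-fold. Cish was detected on 3 of 6 ESdM arrays, and of the 3 BM-DC arrays Tmem176b and Septin3 on 1 and Flt1 and Apoe on 2. The other probes of Flt1 and Sult4a1 were not called, and of those of Septin3 and Amhr2 2 of 4 and 1 of 2 were. ESdM shared no chip with MF or BM-DC.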

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

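In this part the test on sex-linked genes was fixed before its result was seen, and the other tests of the 3 patterns were chosen after. In the groups of more than 3 arrays, MF and CD8 T cells, 42 values were searched for an array far from the rest, and 7 were found where chance gives about 1 in 20. CD8 T cell replicate 2 had 14247 probes detected, against 15814 to 16148 on the other arrays of its group. CD8 T cell replicate 5 had Xist at 4.20 against 10.8 to 11.4, Eif2s3y at 10.8 against 4.17 to 4.41 and Kdm5d at 7.25 against 4.23 to 4.36. Near the detection floor, CD8 T cell replicate 3 had Serpina3f at 4.75 against 4.21 to 4.36 and Amhr2 at 4.81 against 4.26 to 4.38, and MF replicate 1 had Abcc2 at 4.66 against at most 4.33. The Xist, Eif2s3y and Kdm5d values of CD8 T cell replicate 5 are of sex-linked genes on 1 array, so the 7 are not independent of each other. Eif2s3y and Kdm5d without Xist is the state of male cells, and Xist without them, as on the other arrays of the group, that of female cells. The labels give no sex, and no explanation was tested for these values. Among 4162 probes without a single gene symbol, which no comparison of genes uses, 67 were higher on the arrays labelled microglia than in each of the 5 other primary cell groups. Of these 60 were also higher in ESdM, and 57 of the 4162 were called between ESdM and the arrays labelled microglia, 27 higher and 30 lower.

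On the arrays labelled microglia, 11 tested microglia core genes were detected on none. All 11 were detected on every array of another group outside ESdM, 10 of them on all astrocyte arrays. Tested genes had passed the filter of detection on at least 3 arrays, so detection elsewhere was nearly given in advance. For these 11 it shows only that the probes can give signal. Of the untested core genes, Slc2a5 and Crybb1 were detected on no array and Adgrg1 on 2 CD8 T cell arrays. For those, probes that fail to report their gene stay open. In the deposited intensities, less the median of each array, the 10 detected on all astrocyte arrays differed from those arrays by a median of -1.346 (range -5.555 to -0.071). They were chosen by detection p-values that rest on the same intensities, so lower values were nearly fixed and are no separate test. The deposited detection p-values do not depend on the normalization or background correction used here, so neither does the missing detection. An exchange of the microglia and astrocyte labels is excluded, since 10 macrophage lineage genes were higher on the arrays labelled microglia, against 3 lower, and 18 of 19 astrocyte genes were lower. What stays open, untested, is a loss of these genes in culture or another macrophage-like population under this label. A loss of core genes alone would not account for the high Rhox5 or the missing Xist, Eif2s3y and Kdm5d of these arrays, given next.

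Arrays labelled microglia and ESdM shared 284 genes that were higher than in 5 other groups, Rhox5 among them. Of Xist and 3 Y-linked genes, Xist, Eif2s3y and Kdm5d were undetected on all 9 arrays, a state of both Xist and Y-linked RNA that no other group had. That is neither the male nor the female state described above. Uty was near the floor and detected on 2 of the 9, so the test as fixed did not decide. Uty says little here, as 2 of 4 MF and 2 of 3 BM-DC arrays detected it while none detected Eif2s3y or Kdm5d. The shared state of Xist, Eif2s3y and Kdm5d is what the same cell population or cells of 1 origin would give. Separate sources in the same state would give it too, so these cannot be told apart. The groups shared 2 chips with no other group; 0 genes were called between these chips (limma with the chip as a block, 635 at an unadjusted p below 0.05), but an effect of both chips cannot be told apart from the cells. A candidate explanation is an altered copy number of chromosome segments present in both: 3 blocks of 50 neighbouring genes lay outside the permuted range in the same direction in microglia minus MF and in ESdM minus BM-DC, against at most 1 in 1000 permuted gene orders. Median log2 differences were 1.02 and 0.74 for the block from Kif3b to Dbndd2, 1.34 and 1.27 from Ppid to S100a1 and -1.05 and -0.87 from Micu2 to Ipo5. Shared regulation of neighbouring genes would show the same and stays open, untested. Differences without these cells also had blocks outside the permuted range, 2 in MF minus BM-DC and 1 each in astrocyte and neuron minus BM-DC. The other pairs of differences tried, of astrocytes, neurons and CD8 T cells against MF and BM-DC, shared 0 blocks. Of 22 named microglia core genes, 14 were detected on no array labelled microglia and 11 on no array of each ESdM line. For these genes this argues against a microglial identity shared by both cell sources, although their loss in culture stays open, untested.

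Interferon response genes were higher on the arrays labelled microglia than in ESdM. The chip as the source is excluded, since 14 of the genes were called with the chip as a fixed block. A single array is excluded too, with at least 13 called when any array was left out. Of 128 markers of 9 other cell types, 3 were lower in ESdM (Cd40, Slamf7 and Ly6c1) and 2 higher. The median difference of microglia minus ESdM was -0.013 over these markers. This argues against RNA of those 9 cell types as the whole cause. The macrophage lists were not among the 9, so RNA of other macrophages or monocytes was not tested. The interferon genes called had a median difference of 3.07. They were selected as lower in ESdM, so that gap is no separate test. The hypothesis that the cells under the microglia label had met interferon or an immune stimulus in culture stays open, and no biological explanation was tested.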

How the results depend on the processing

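The signature without the astrocyte comparison, the interferon count and the alternatives for named genes outside ESdM vs microglia and the signature were added after the data were seen; the other alternatives were fixed before. Of 202 alternatives for the main counts, leaving single arrays out aside, 140 stayed within 1.5 times the main value and kept their side of the threshold, and 62 did not; the cause was not tested except where stated. No named gene reversed. In the order ESdM, ESdM 20 and ESdM 22 vs microglia, then microglia vs MF, BM-DC, astrocyte, neuron and CD8 T cell, ESdM vs MF and BM-DC, signature and shared signature, counts without background correction were 122, 124, 118, 1580, 2035, 2744, 3307, 2600, 1702, 2287, 193 and 157. On the series matrix values they were 105, 112, 106, 1440, 1868, 2552, 3073, 2394, 1563, 2115, 177 and 140. With all probes tested as probes, which tests more items, they were 438, 468, 419, 4689, 5717, 7307, 8539, 7328, 4896, 6272, 599 and 483. With no minimum fold, a looser threshold by construction, they were 1564, 1197, 1157, 6180, 6432, 7575, 7958, 7427, 6945, 7258, 1012 and 884, and 3 for ESdM 22 vs ESdM 20. With normexp at offset 50 the counts that moved were 146, 152 and 148 for ESdM, ESdM 20 and ESdM 22 vs microglia, 1895 for microglia vs MF and 1979 for ESdM vs MF. Median scaling gave 221 signature genes, 175 shared and 1 call for ESdM 22 vs ESdM 20, and shifted the median of all genes in microglia vs MF to -0.123. It turned the majority of calls from higher to lower in microglia vs BM-DC (1537 higher, 1900 lower), microglia vs CD8 T cell (1768, 2536) and ESdM vs BM-DC (1743, 1993), and gave 755 higher and 2499 lower for microglia vs MF and 853 and 2465 for ESdM vs MF. The near-even majority of microglia vs neuron also turned to lower with normexp at offset 50 (1872, 1931), without background correction (1600, 1707), on the series matrix values (1477, 1596) and without neuron replicate 1 (2555, 2576), and that of microglia vs astrocyte to higher with all probes (3839, 3468). With no minimum fold it turned to higher in ESdM vs microglia (814, 750), ESdM 20 vs microglia (636, 561), microglia vs MF (3180, 3000), microglia vs astrocyte (3792, 3783) and ESdM vs MF (3629, 3316). ESdM 22 vs ESdM 20 also had 1 call with the chip as a fixed block. ESdM, ESdM 20 and ESdM 22 vs microglia had 174, 73 and 139 calls on the second shared chip alone (2, 1 and 2 arrays labelled microglia, ESdM 20 and ESdM 22), and 270, 289 and 322 on the first (1, 2 and 1 arrays), where a lone array is assumed to vary like the others. With an estimated correlation 4 lists of 9 were called between ESdM and the arrays labelled microglia. Of the 265 genes called in ESdM vs microglia 29.06% were higher, against 52.05% with no minimum fold and 19.05% on the series matrix values. The distance of MF minus that of ESdM was 0.415 on the series matrix values to 0.736 with median scaling, and 0.116 as 1 minus the Spearman correlation. Leaving out each array in turn gave 249 to 274 for ESdM vs microglia, 254 to 284 for ESdM 20, 246 to 304 for ESdM 22, 2851 to 2959 for microglia vs MF, 3440 to 3607 for BM-DC, 4519 to 4570 for astrocyte, 5131 to 5230 for neuron, 4191 to 4251 for CD8 T cell, 2979 to 3100 for ESdM vs MF, 3763 to 3874 for ESdM vs BM-DC, 341 to 355 for the signature, 276 to 290 shared, 0.6288 to 0.6531 for the distance, 8 to 9 lists, and 0 to 1 for ESdM 22 vs ESdM 20, which had 1 call without ESdM 20 replicate 1 or 2 or ESdM 22 replicate 3. Of 440 alternatives for named genes of ESdM vs microglia 5 lost the call (ND4L, Abcc3, Mir17hg) and 435 kept it; it was kept in 3178 of 3200 in the other comparisons and in 465 of 465 for the signature. The call of ND4L, ESdM 20 vs microglia, was lost with 4 other forms of background correction or normalization (adjusted p 0.0565 to 0.158) and on leaving out any 1 of 5 of the 6 arrays (0.0545 to 0.0836). The interferon count was 9 without background correction and on the series matrix values. Same-numbered arrays had correlations of -0.13 to 0.11, so the numbers do not pair the samples. With the replicate number as a block the counts were 267, 278, 269, 0 for ESdM 22 vs ESdM 20, 2924, 3500, 4537, 5192, 4262, 3060, 3798, 348 and 286, and 9 lists; it changed no other call. Signal over background limits genes near 4.3: a fold is a bound where no array of the lower group detected the gene, and a fitted fold against a group detected on only some arrays rests partly on values at the floor.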

Other observations

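The lists of genes lower than in every other group were drawn up, and the genes named from them and the pluripotency counts and CD8 T cell arrays chosen, after the values were seen; the splits of the arrays were fixed before. A set of 115 genes was lower on the arrays labelled microglia, and 132 in ESdM, than in each of astrocytes, neurons, MF, BM-DC and CD8 T cells, and 102 were in both sets, where independent sets would share 1.18. Both sets use the same 5 groups for comparison. Lamtor4, a subunit gene of the lysosomal Ragulator complex, Prkd3, a kinase gene, and Acss1, a mitochondrial acetyl-CoA synthetase gene, were undetected on the arrays labelled microglia and at 9.14, 7.96 and 7.65 or more in the 5 groups. Chchd10, a mitochondrial gene, was detected on 1 array labelled microglia and at 8.81 or more in the 5 groups. Sgk1, a kinase gene induced by glucocorticoids, was at 5.43 with a smallest difference of -4.74. The immediate early gene Egr1 and Cd47, which signals against phagocytosis, had smallest differences of -2.745 and -1.84. The receptor genes Notch1 and Axl were undetected on these arrays and at 6.70 and 6.57 or more in the 5 groups. Xist was at 4.35 on the arrays labelled microglia, 4.24 in ESdM 20 and 4.29 in ESdM 22, against 8.16 in astrocytes, 8.30 in neurons, 10.71 in MF and 9.39 in BM-DC, and astrocyte and neuron arrays also carried Eif2s3y at 8.09 and 8.08.

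Of 22 pluripotency genes named on the array, 2 were detected on all arrays labelled microglia and all ESdM 20 arrays (Dnmt3l and Klf4) and 3 on all ESdM 22 arrays (with Zfp42). MF and BM-DC had 2 each. CD8 T cell replicates 1 and 3 had more RNA of macrophage lineage genes than the other 3 arrays of their group, with Adgre1 at 7.34 and 7.82 against 4.48 to 5.05, Fcer1g at 7.61 and 7.78 against 5.08 to 5.99, C1qb at 6.87 and 6.65 against 4.44 to 4.91 and Csf1r at 6.93 and 7.31 against 4.71 to 5.46. Ptprc was at 6.78 on replicate 2 and at 9.78 to 11.07 on the others. No explanation was tested.

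Splits of the arrays into groups of the same sizes were refitted, with the other groups kept. For ESdM vs microglia 1 of 84 splits, the real one with 265 genes, gave as many, and the highest other gave 1. That share is below 0.05 and the smallest the splits allow. The same held for microglia vs MF (1 of 35 splits, 2882 genes, highest other 2084) and microglia vs CD8 T cell (1 of 56, 4205, highest other 2439). It held for ESdM vs MF (1 of 100 drawn, 3030, highest other 1668) and ESdM vs BM-DC (1 of 84, 3797, highest other 732). It also held for the signature (1 of 100 drawn, 348, highest other 1) and the shared signature (1 of 100 drawn, 284, highest other 0). For both, the labels of all groups involved were redrawn, so each drawn group mixed cell types. Few genes can then be higher than in every other group. A value near 0 was thus nearly fixed in advance and is no support for either set. These shares were not adjusted over the comparisons. If the replicates are technical, they show only that arrays of 1 preparation resemble each other. For the gene lists in ESdM vs microglia 3 of 84 splits gave at least 9 lists, the highest other 10, a share below 0.05. With 10 splits, which are too few for a share under 0.05, ESdM 20 vs microglia gave 276 and at most 0 otherwise, ESdM 22 vs microglia 267 and 0, ESdM 22 vs ESdM 20 0 in all 10, microglia vs BM-DC 3499 and 0, microglia vs astrocyte 4536 and 0, and microglia vs neuron 5192 and 0.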
